A study of Rattus norvegicus with 6 samples.

How the data were processed

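The samples were 6 RNA-seq libraries from rat sciatic nerve, 3 labelled with a PCL conduit without ultrasound and 3 with a PLLARS conduit and ultrasound. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol, poly(A) RNA was enriched, NEB Next Ultra libraries were made from fragmented RNA with random primers, and paired-end reads were sequenced on a NovaSeq instrument. The kit as named does not state strand, so reads of overlapping antisense genes cannot be told apart. The time between surgery and collection, batch and date were not given in the sources used here. Conduit material and ultrasound differed together between the groups, so no comparison separates them.

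The deposited values were FPKM per gene model, as the name of the deposited workbook states, with 1 column per library and no pooling, in a table of 21028 gene models with rat Ensembl identifiers, Entrez identifiers, positions and symbols. Per the submitters' processing notes, FastQC 0.11.5, HISAT2 2.1.0, StringTie 1.3.3b and DESeq 1.28.0 were used; the notes give no roles or order. They name the build hg38, a human build, while the identifiers are rat, so the build of the positions is not settled and positions are printed as deposited. A second sheet held the same values in all 21028 rows and was not used. For 16620 gene models with an Entrez identifier, 16536 were found in a RefSeq gene table of the rat assembly GRCr8, which was used for older symbols and gene types only.

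No counts were analysed here, so no count model was fitted. For 445 small single-exon models (U RNA, 7SK, 5S rRNA, snoRNA and microRNA names, none longer than 360 bases) FPKM times length gave whole multiples of a fixed step in each library: 1123 of 1123 values under 50 fragments came within 0.03 of a whole number. The step gave totals of 15320000, 15900000 and 16690000 fragments for PCL replicates 1 to 3 and 16360000, 16170000 and 15640000 for PLLARS_US replicates 1 to 3, rounded to 10000. For other models only 36.2% of such values came out whole on the length of the gene span, so fragment counts were not recovered for most genes. An FPKM of 1 for a model of 1000 bases thus stands for about 15 to 17 fragments.

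FPKM values were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), for the 13720 genes with a mean FPKM of at least 1 over the 6 libraries, with group as the only term, a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. Log2 differences are on that scale and understate the change of low genes. The 38 gene lists, fixed before the data were examined, were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists, and compared with camera at an estimated correlation and with fry. Camera compares a list with the other genes, and fry tests whether a list's genes move one way on balance. Means are of FPKM with the SD of 3 rats. Exact permutation tests of 3 against 3 libraries cannot give a p below 0.1. The design also named an analysis of annotation terms, which was not run because the table held no such terms.

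Genes were named by a rule fixed before the data were examined. It took the 12 genes of largest change in each direction among those that passed, with non-overlapping groups, a mean FPKM of at least 5 in the higher group and a gene symbol. With fewer than 5 passing, it took the 12 with the smallest p at the same floor, and this applied in both directions. It added up to 4 members of each list by p, and 2 further members by level of each list that passed. The rule took 177 genes, which were followed under each alternative for single genes that kept them among the tested genes, and the text gives values for part of them. The result for 1 gene taken by the rule is not reported here.

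The fit was tested on simulated data with 13525 genes. Of 100 genes changed by a log2 difference of 1, 46% were recovered, and of 100 changed by 2, 87% were recovered, each time with the sign right in 100%, and 9 unchanged genes were called in all. None of 37 unchanged lists was called. The changed genes were drawn from those with a mean level above about 5 FPKM. Noise was drawn independently for each gene, and the lists were random genes. These figures therefore do not measure errors or power under the correlation between genes and the tissue differences of the real libraries. Alternatives covered the pseudocount (0.1 and 0.5), the filter (none, and a mean FPKM of at least 5), rescaling the libraries to 1 common FPKM sum, median-ratio scaling, quantile normalization, no trend, robust moderation, array weights, a replicate block, named gene models alone and leaving out each library. After seeing the data, 2 alternatives were added: leaving out the 2 libraries richest in skeletal muscle RNA, and the muscle level as a covariate. Also added after seeing the data were 6 lists: MHC class I antigen processing, nucleic acid sensors, interferon-inducible GTPases, interferons with their receptors, splicing factors by gene description and cytoplasmic ribosomal proteins. These lists were also tested without the genes already named for the smallest p and without members of the interferon list, and their adjusted p values, which cover 6 lists, are given from that form.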

Results

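Gene expression was measured by RNA sequencing of poly(A)-enriched RNA from the sciatic nerve of 6 female rats whose nerve defect was bridged by a tubular conduit. The 3 rats of the PCL group received a PCL conduit and no ultrasound, and the 3 rats of the PLLARS_US group received a PLLARS conduit and ultrasound stimulation. The series title describes the tested device as piezoelectric, meaning that it turns mechanical vibration into electrical charge, and as based on Rochelle salt. The 6 libraries were taken as 1 per rat, and their values were deposited as FPKM, fragments scaled to the length of the gene model and to the depth of the library. The steps between low FPKM values of single-exon models placed the depth at about 15320000, 15900000 and 16690000 fragments for PCL replicates 1 to 3 and at about 16360000, 16170000 and 15640000 for PLLARS_US replicates 1 to 3. The libraries listed between 13146 and 13800 genes at an FPKM of at least 1.

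The comparison of PLLARS_US with PCL asked how the nerve transcriptome differed between the device with ultrasound and the plain conduit. Of the 12 genes with the smallest p among those higher in the PLLARS_US libraries, with a gene symbol and a mean FPKM of at least 5 in the higher group, 5 belonged to the list of interferon-stimulated genes fixed before the data were examined. Mx2, an antiviral GTPase, had an FPKM of 16.5 ± 4.59 in the PCL group and 198 ± 60.4 in the PLLARS_US group (SD, n = 3 each), a log2 difference of 3.48 (SE 0.31). Oas1a, which makes the oligoadenylates that activate RNase L, stood at 6.10 ± 1.14 against 33.6 ± 6.24 FPKM, a log2 difference of 2.28 (SE 0.20). Among the genes lower in the PLLARS_US libraries the smallest p was that of Rsrp1, an arginine- and serine-rich protein gene, which had 103 ± 5.47 FPKM in the PCL group and 55.5 ± 3.87 in the PLLARS_US group, a log2 difference of -0.88 (SE 0.12). None of these single genes passed the threshold. With limma and Benjamini-Hochberg adjustment, 0 of 13720 tested genes had an adjusted p under 0.05, the smallest being 0.113. An unadjusted p under 0.05 was reached by 960 genes (273 higher and 687 lower), where 686 would be reached by chance on average. Under median-ratio scaling the 933 genes at that unadjusted level split into 425 higher and 508 lower, and under quantile normalization 969 split into 406 and 563. Without PCL replicate 2 there were 578 such genes, and without PLLARS_US replicate 3 there were 615.

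With the same floor and a gene symbol, the 12 genes with the smallest p in the higher direction were Oas1a, Mx2, Rtp4, Apol9a, Irgm, Eif2ak2, Ifih1, Ddx58, Isg15, Oasl2, Cxcl10 and Pml, with limma adjusted p from 0.113 to 0.214. In each of them all 3 PLLARS_US libraries lay above all 3 PCL libraries. Isg15, a ubiquitin-like modifier, had 7.79 ± 0.435 FPKM in the PCL group and 69.7 ± 31.5 in the PLLARS_US group, a log2 difference of 2.89 (SE 0.36). Cxcl10, a chemokine that attracts T cells, had a log2 difference of 2.34 (SE 0.30), and Rtp4 had 9.04 ± 1.65 against 44.3 ± 10.9 FPKM. The cytosolic RNA sensors Ifih1 and Ddx58 differed by 1.12 (SE 0.14) and 1.61 (SE 0.20) on the log2 scale. Eif2ak2, the double-stranded RNA-activated kinase that blocks translation, differed by 1.03 (SE 0.12), the GTPase gene Irgm by 1.01 (SE 0.12) and Pml by 1.01 (SE 0.13). By the positions in the deposited table, whose genome build is not settled by the sources used here, Mx2 (ENSRNOG00000001963) lay on the plus strand of chromosome 11 from 38035450 to 38059950. Oas1a (ENSRNOG00000001369) lay on the plus strand of chromosome 12 from 41200718 to 41211909, and Isg15 (ENSRNOG00000021802) on the minus strand of chromosome 5 from 173624310 to 173626248. Mx2 and Oas1a have close paralogs, so part of their signal may depend on how shared reads were assigned, which was not tested.

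With the same floor and a gene symbol, the 11 genes with the smallest p in the lower direction were Rsrp1 (ENSRNOG00000017309, plus strand of chromosome 5 from 153260930 to 153264669), Leng8, a U6 model, a U1 model, Snrnp70, Sema6b, Tmem202, Apbb3, Cox20, Fnbp4 and Arglu1, with limma adjusted p from 0.214 to 0.244. Snrnp70, a protein of the U1 small nuclear ribonucleoprotein, had 103 ± 9.35 FPKM in the PCL group and 59.0 ± 1.12 in the PLLARS_US group, a log2 difference of -0.78 (SE 0.12). Leng8 had 43.8 ± 5.81 against 20.2 ± 1.75 FPKM, and Arglu1, which binds splicing regulators, had 59.6 ± 4.91 against 36.7 ± 1.25. Sema6b, a transmembrane semaphorin, had 12.5 ± 0.210 against 7.20 ± 0.267 FPKM. The U6 and U1 models are 2 of many near-identical copies, and poly(A) enrichment does not select such RNAs. Across the tested genes, 594 had all PLLARS_US libraries above all PCL libraries and 1378 had them below, 14.4% together. The average over the 10 splits of the libraries into 3 and 3 is 10%. Genes vary together, so a single split can lie well away from that average, and 14.4% does not show an excess over chance. With limma array weights, which down-weight the more variable libraries, 118 genes had an adjusted p under 0.05 (41 higher and 77 lower), among them all 24 genes taken by the rule for the smallest p. The count was 3 without PLLARS_US replicate 2: Ifit3, Isg15 and Mx1, of which Ifit3 and Mx1 were named after their values were seen.

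**Figure D1:**
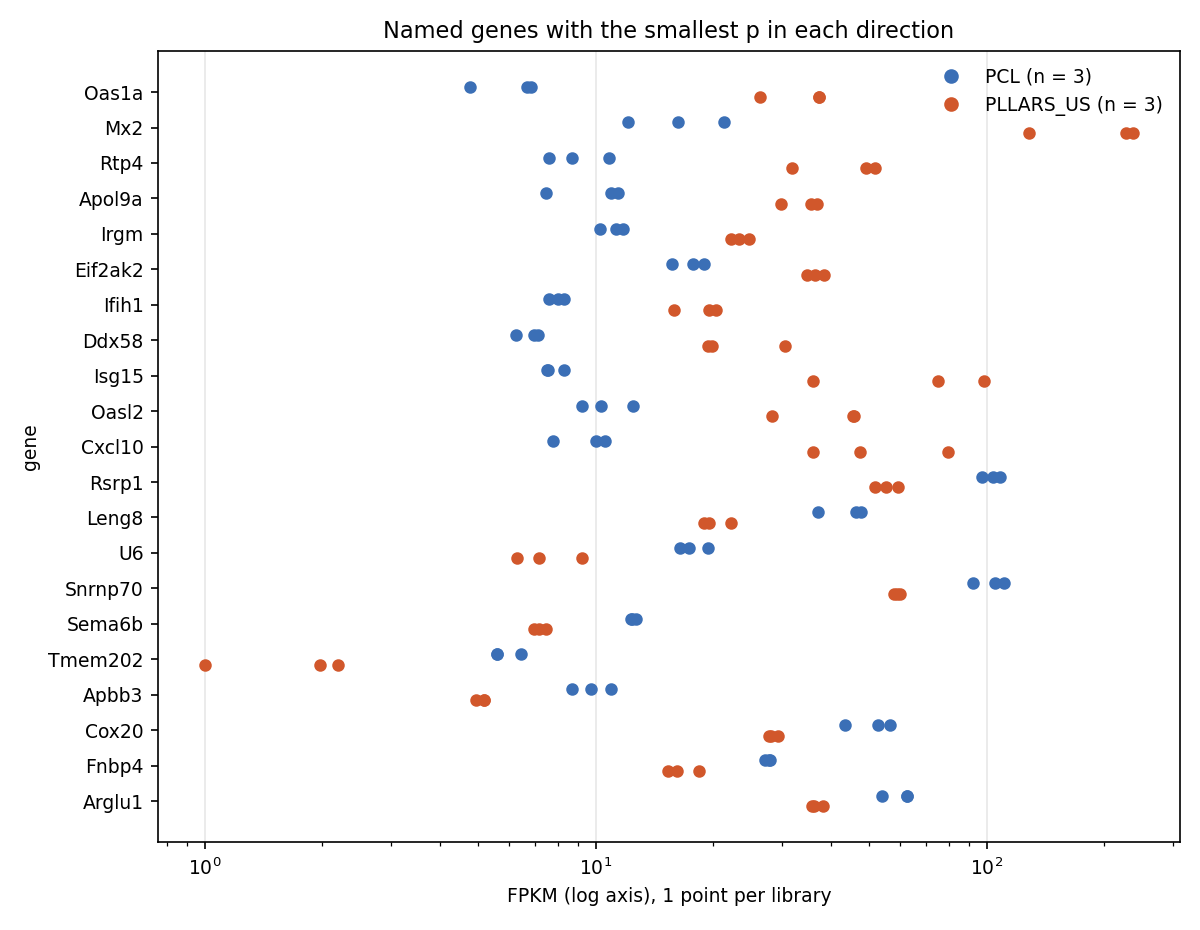
FPKM on a log axis of the 11 genes with the smallest p in each direction, among those with a gene symbol and a mean FPKM of at least 5 in the higher group, 1 point per library, PCL in blue and PLLARS_US in orange. The U1 model is left out because it is listed at 0 in a PLLARS_US library. In each gene drawn the libraries of the groups do not overlap, as for Mx2 with 12.1 to 21.2 in PCL and 128 to 237 in PLLARS_US.

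Of the 38 gene lists fixed before the data were examined, the interferon-stimulated genes stood furthest above the rest. They rose as a list in the PLLARS_US libraries: 19 of 20 tested members were higher, with a median log2 difference of 1.76 (quartiles 1.04 and 2.40). The camera test gave an adjusted p of 1.7e-32 at its preset correlation and fry an adjusted p of 0.0497, but the camera call was lost, with an adjusted p = 0.416 with an estimated correlation. Splits of the libraries that mix the groups called 9 to 18 lists with camera at the preset correlation. Its small adjusted p values, here and below, are therefore weak evidence alone. In 16 members of the interferon list all PLLARS_US libraries lay above all PCL libraries. Beside Mx2 and Oas1a, Irf7, the transcription factor that amplifies interferon production, had 46.7 ± 28.4 FPKM in the PCL group and 318 ± 141 in the PLLARS_US group. Ifi27, the list's most abundant member, had 361 ± 44.9 against 739 ± 138 FPKM. Ifit1 was the member that was lower, with 0.2, 5.4 and 4.3 FPKM in the PCL libraries and 1.1, 0.1 and 0.0 in the PLLARS_US libraries (named after its values were seen). Adjusted over the list alone, 17 members passed with limma, all higher, and 0 passed over all genes tested, where 18 had an unadjusted p under 0.05.

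Cell division genes fell as a list by camera at its preset correlation (adjusted p 2.3e-09), with an adjusted p = 0.785 with an estimated correlation and a fry adjusted p of 0.123. All 21 tested members were lower in the PLLARS_US group, with a median log2 difference of -0.53 (quartiles -0.67 and -0.27), and 11 had no overlap between the groups. The kinase Cdk1, which drives entry into mitosis, had 10.2 ± 1.05 FPKM in the PCL group and 5.73 ± 1.08 in the PLLARS_US group. Birc5, a protein of the chromosomal passenger complex, had 5.87 ± 0.807 against 2.85 ± 0.760 FPKM, Ccnb1 7.34 ± 0.851 against 4.36 ± 0.540 and Cenpf 2.65 ± 0.357 against 1.24 ± 0.136. The abundant replication genes Pcna, at 63.3 ± 4.91 against 61.6 ± 7.15 FPKM, and Mcm6, at 10.6 ± 1.04 against 10.2 ± 1.53, differed by less than their spread. Adjusted over the list alone, 7 members passed with limma, all lower, and 0 over all genes, with 9 at an unadjusted p under 0.05.

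The inflammatory cytokine, chemokine and enzyme list had 14 of 22 members higher and a median log2 difference of 0.33 (quartiles -0.07 and 0.93). It passed camera at the preset correlation (adjusted p 0.0278), with an adjusted p = 0.949 with an estimated correlation and a fry adjusted p of 0.982. Its members with the smallest p were Cxcl10 and Cxcl11, both interferon-inducible chemokines, and Cxcl11 had 1.18 ± 0.387 FPKM in the PCL group and 4.12 ± 2.63 in the PLLARS_US group. Il1b had 8.41 ± 4.74 against 25.5 ± 21.0 FPKM and Il1a 0.199 ± 0.178 against 2.45 ± 3.00, each with its highest value in PLLARS_US replicate 1. Ccl2, a monocyte chemokine, had 36.4 ± 10.2 against 52.3 ± 22.7 FPKM, and Ccl3 45.9 ± 33.6 against 38.7 ± 51.5. Adjusted over the list alone, Cxcl10 was the 1 member that passed with limma, and 0 passed over all genes, with 2 at an unadjusted p under 0.05. The list rested on PLLARS_US replicate 1, without which its median was -0.03 and its adjusted p 0.964, and that library also had the highest mean of the neutrophil list, 4.69 against 2.35 to 2.88 in the others on log2(FPKM + 1). The call was also lost without PCL replicate 1 (median 0.31, adjusted p 0.0528), without both PCL replicate 3 and PLLARS_US replicate 1 (median -0.08, adjusted p 0.961) and under median-ratio scaling (median 0.40, adjusted p 0.107), and the median was 0.13 without PCL replicate 3.

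Osteoclast and foreign body giant cell genes had 13 of 14 members lower and a median log2 difference of -0.87 (quartiles -1.38 and -0.58). The list passed camera at the preset correlation (adjusted p 0.0381), with an adjusted p = 0.949 with an estimated correlation and a fry adjusted p of 0.982. Mmp9, a gelatinase, had a log2 difference of -2.56 (SE 1.18), with a mean FPKM of 233 in the PCL group and 27.2 in the PLLARS_US group. Acp5, the tartrate-resistant acid phosphatase, had 118 ± 89.1 against 42.4 ± 28.0 FPKM, and the proton pump subunit Atp6v0d2 had 63.1 ± 62.7 against 14.7 ± 15.3. Itgb3, an integrin chain, had 16.8 ± 6.95 against 8.81 ± 1.01 FPKM and was the member without overlap between the groups. Gpnmb had 2088 ± 1868 against 785 ± 670 FPKM and Spp1, the osteopontin gene, 2956 ± 2194 against 1815 ± 2086. No member passed with limma over the list alone or over all genes, and 1 had an unadjusted p under 0.05. PCL replicate 3 held the highest list mean, and without it the median was -0.43 and the adjusted p 0.609, while without PLLARS_US replicate 1 the median was -1.65. The call was also lost without PLLARS_US replicate 3 (median -0.44, adjusted p 0.656), without PLLARS_US replicate 2 (median -0.89, adjusted p 0.119) and with no filter on low values (median -0.73, adjusted p 0.144).

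**Figure D2:**
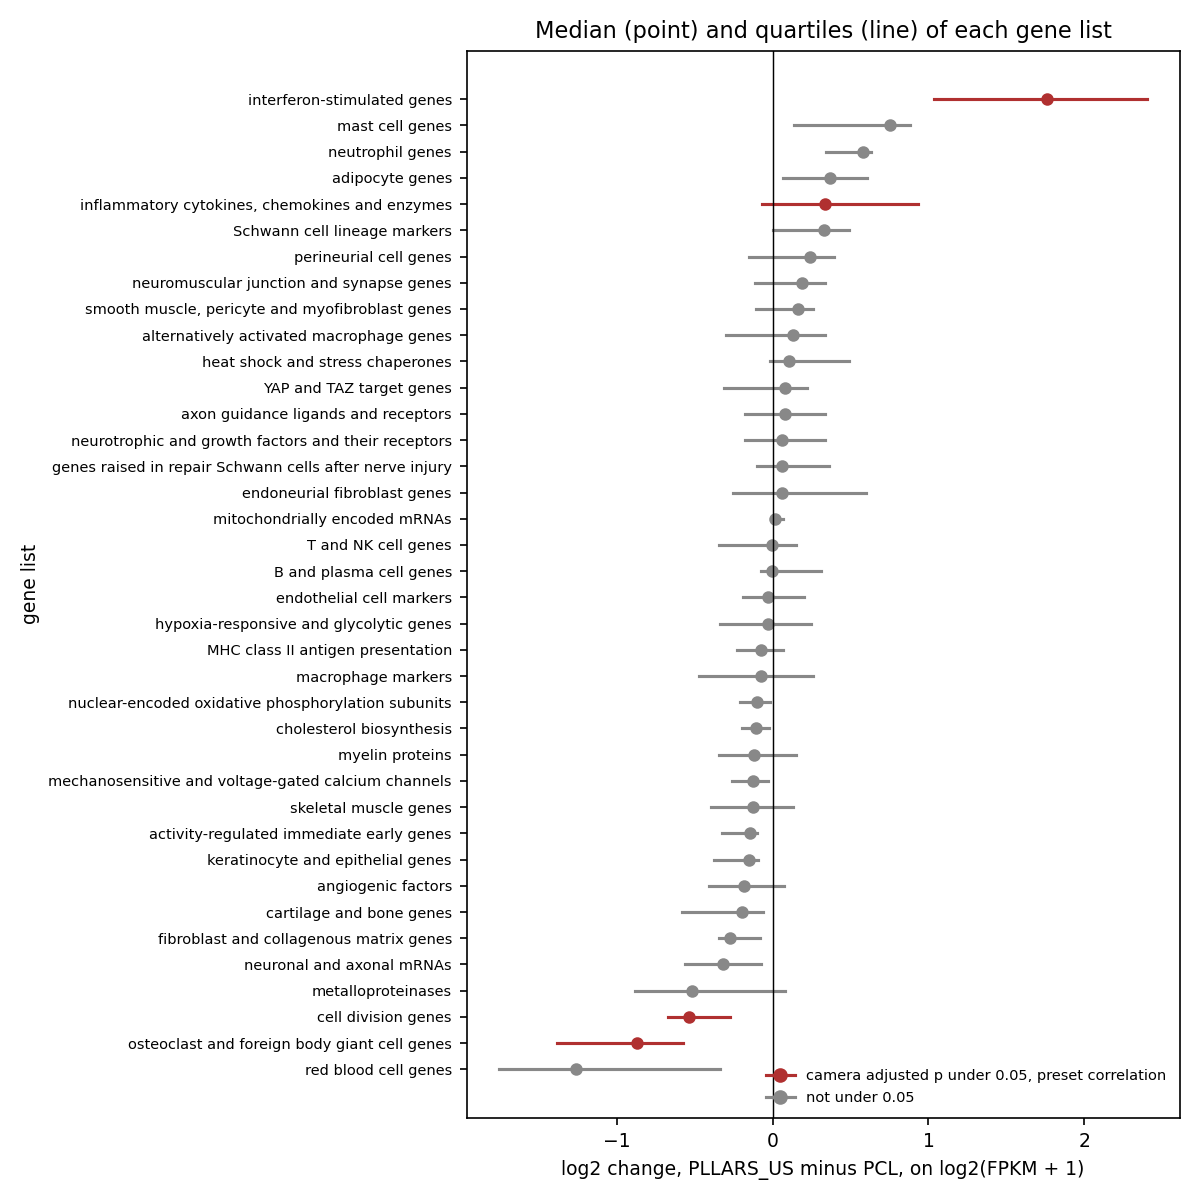
Median log2 difference of PLLARS_US minus PCL for each of the 38 gene lists (points) with the quartiles of its members (lines). Red marks the 4 lists with a camera adjusted p under 0.05 at the preset correlation. The interferon-stimulated genes have a median of 1.76 and the red blood cell genes, which did not pass, one of -1.26.

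The libraries also differed in tissue makeup in ways that did not follow the groups. Skeletal muscle genes had a mean log2(FPKM + 1) of 7.38 in PCL replicate 3 and 7.64 in PLLARS_US replicate 1, with 5.77 in PLLARS_US replicate 3, 5.09 in PCL replicate 2, 2.37 in PCL replicate 1 and 0.95 in PLLARS_US replicate 2. Acta1, the skeletal muscle actin, ran from 2.1 FPKM in PLLARS_US replicate 2 to 4632 in PLLARS_US replicate 1 (named after its values were seen). The 2 libraries with the highest muscle level, called muscle-rich here although others also held muscle RNA, had the lowest means of repair Schwann cell genes, 2.57 and 2.98 against 4.33 to 4.43 in the others, and of fibroblast matrix genes, 7.40 and 7.42 against 8.07 to 8.45. Myelin genes stood at 3.42 in PCL replicate 1 and 3.46 in PLLARS_US replicate 2, and at 5.48 to 5.82 in the other libraries. Red blood cell genes were highest in PCL replicate 1, at 7.07, and in PLLARS_US replicate 1, at 7.02, and lowest in PLLARS_US replicate 2, at 1.64. The first principal component held 52.2% of the variance and placed PCL replicate 3 and PLLARS_US replicate 1 at one end. The second held 18.6% and kept the groups apart, with PCL libraries at 17.5 to 31.1 and PLLARS_US libraries at -30.4 to -6.35. Pearson correlations across genes between libraries of the same group ran from 0.862 to 0.960 and between groups from 0.868 to 0.959. Without the 2 muscle-rich libraries, a choice made after seeing the data, limma called 0 genes with 1867 at an unadjusted p under 0.05, and camera called 10 lists. Leaving out single libraries, camera called 12 lists without PCL replicate 3, 11 without PLLARS_US replicate 1 and 8 without PLLARS_US replicate 2 or 3, against 4 with all libraries. The interferon median was 1.53 without the 2 muscle-rich libraries.

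**Figure D3:**
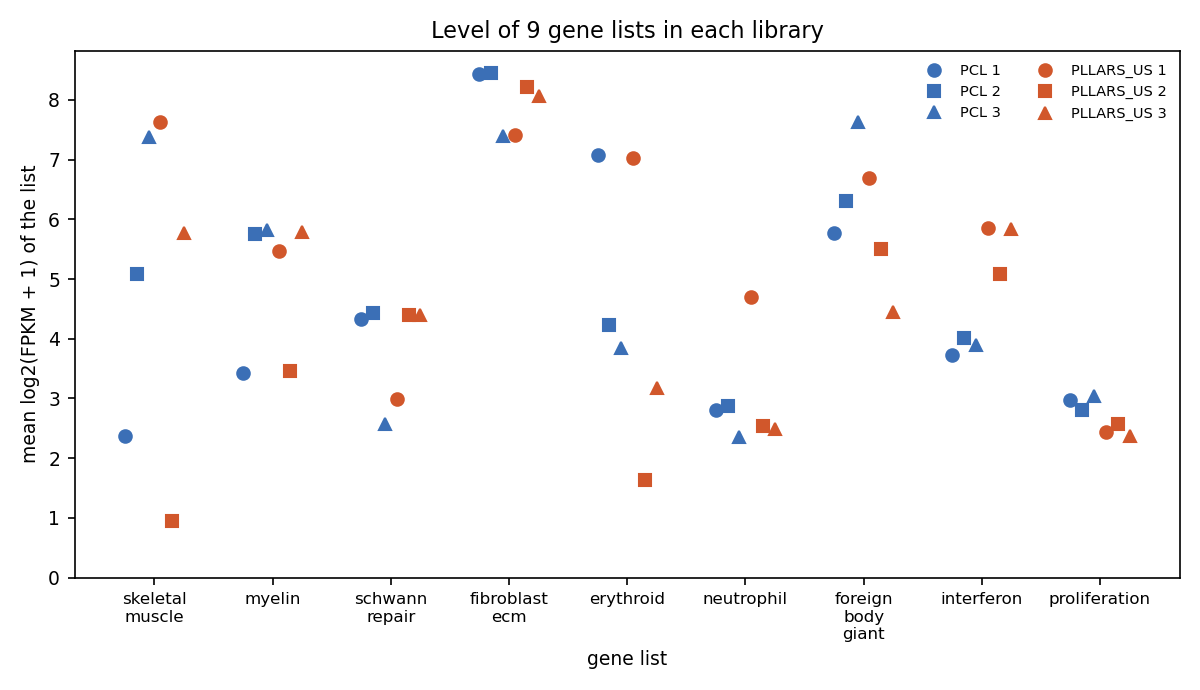
Mean log2(FPKM + 1) of 9 gene lists in each library, PCL in blue and PLLARS_US in orange, with circles, squares and triangles for replicates 1, 2 and 3. Skeletal muscle genes span 0.95 to 7.64 within the PLLARS_US group, while the interferon list keeps the groups apart, at 3.73 to 4.02 in PCL and 5.08 to 5.86 in PLLARS_US.

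The lists of nerve cells did not pass the camera test. Schwann cell lineage markers had a median log2 difference of 0.33, with Itgb8 at 75.6 ± 52.6 FPKM in the PCL group and 175 ± 120 in the PLLARS_US group and the calcium-binding protein gene S100b at 173 ± 25.5 against 241 ± 110. Without PCL replicate 3 that median was -0.0034, without PLLARS_US replicates 2 and 3 in turn 0.13 and 0.086, without PCL replicate 2 0.49, and without PLLARS_US replicate 1 0.81 with a camera adjusted p of 0.0196. The Schwann lineage list passed in 2 of 15 alternatives, with a lowest camera adjusted p of 0.00047. Myelin genes had a median of -0.12, with the myelination regulator Egr2 at 29.6 ± 15.1 against 16.5 ± 5.42 FPKM. The myelin median was -0.94 without PCL replicate 1, -0.49 without PLLARS_US replicate 3, 0.31 and 0.35 without PCL replicates 2 and 3 in turn, and 0.74 without PLLARS_US replicate 2, where the list passed with a camera adjusted p of 0.0141. Repair Schwann cell genes had a median of 0.06, with Jun, the transcription factor that drives the repair state, at 128 ± 51.2 against 181 ± 48.0 FPKM. Neuronal and axonal mRNAs, of which 7 of 22 were abundant enough to be tested, had a median of -0.32, with the growth cone gene Stmn2 at 13.4 ± 4.30 against 6.70 ± 4.39 FPKM. Over 15 alternatives the neuronal median ran from -0.43 to -0.025. Neurotrophic factors and receptors had a median of 0.06, with the receptor gene Lifr at a log2 difference of 0.76 and the growth factor gene Hgf at 5.23 ± 0.640 against 3.59 ± 0.108 FPKM, both without overlap between the groups but neither passing over the list alone (limma adjusted p 0.256 for both). Axon guidance genes had a median of 0.08, perineurial genes 0.24, endoneurial fibroblast genes 0.06 and neuromuscular junction and synapse genes 0.19. Without PLLARS_US replicate 1 the repair Schwann cell list (median 0.48, camera adjusted p 0.0196) and the perineurial list (0.33, adjusted p 0.0354) passed and the synapse median was -0.19. Without PCL replicate 3 the medians of the repair Schwann cell, neurotrophic, axon guidance and endoneurial lists were -0.55, -0.16, -0.11 and -0.21, and without PLLARS_US replicate 3 those of the repair, neurotrophic and endoneurial lists were -0.06, -0.21 and -0.12. Without PLLARS_US replicate 2 the repair, neurotrophic and axon guidance medians were -0.096, -0.029 and -0.012. The camera adjusted p of these 9 lists ran from 0.248 to 0.855, and 0 of their members passed with limma over the list alone.

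Immune cell lists other than those above did not pass either. Macrophage markers had a median log2 difference of -0.08, although Aif1 had 36.4 ± 6.32 FPKM in the PCL group and 51.8 ± 7.16 in the PLLARS_US group without overlap. Alternatively activated macrophage genes had a median of 0.13, with Il10 at 7.35 ± 2.34 against 2.44 ± 2.89 FPKM and F13a1 at a log2 difference of 0.91. Neutrophil genes had a median of 0.58 and a camera adjusted p of 0.0586, with Lcn2 at 8.22 ± 1.65 against 27.6 ± 27.2 FPKM, and the difference rested on PLLARS_US replicate 1, without which the median was -0.032. The median of T and NK cell genes was -0.0036, that of B and plasma cell genes -0.0046, that of MHC class II genes was -0.08, that of mast cell genes 0.75 and that of red blood cell genes -1.26. The mast cell median was 0.068 without PLLARS_US replicate 3, 0.32 without PCL replicate 3, and 1.31 without PLLARS_US replicate 1, where the list passed with a camera adjusted p of 0.00349. The red blood cell median was -0.11 without PCL replicate 1, 0.057 without PLLARS_US replicate 2 and -2.83 without PLLARS_US replicate 1, where the list passed with a camera adjusted p of 9.7e-05. That list also passed with the replicate block (adjusted p 0.00142) and without the 2 muscle-rich libraries (median -3.39, adjusted p 0.00045). Other lists passed without PLLARS_US replicate 2, the neutrophil list with a median of 0.89 (adjusted p 0.00583) and the MHC class II list with -0.44 (adjusted p 0.0294), and without PLLARS_US replicate 3, the neutrophil list with 0.90 (adjusted p 0.00042) and the macrophage list with 0.15 (adjusted p 0.0440). The macrophage list also passed without PCL replicate 3 (median 0.11, adjusted p 0.0486), and the MHC class II median was 0.24 without PLLARS_US replicate 3. Adjusted p values by camera for these lists other than the neutrophil list ran from 0.175 to 0.895.

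Among matrix and vascular genes, metalloproteinases and their regulators came nearest to the threshold, with 15 of 22 lower, a median log2 difference of -0.52 and a camera adjusted p of 0.0586. The stromelysin and collagenase genes Mmp10, Mmp3 and Mmp13 were lower in all PLLARS_US libraries than in any PCL library, and Mmp13 had 47.6 ± 13.4 FPKM in the PCL group and 11.7 ± 9.22 in the PLLARS_US group. No member passed with limma over the list alone, the smallest adjusted p being 0.143. The list passed camera in 7 of 15 alternatives, among them leaving out PCL replicate 3 (adjusted p 0.00994), PLLARS_US replicate 1 (adjusted p 0.00811) or PLLARS_US replicate 2 (adjusted p 0.0294), with adjusted p from 0.00517 to 0.949 over all 15, and its median was -0.090 without PLLARS_US replicate 3. Fibroblast and collagen genes had a median of -0.28, endothelial markers -0.03, mural cell genes 0.16 and angiogenic factors -0.19, with camera adjusted p values from 0.262 to 0.742. The fibroblast list passed without PCL replicate 3 (median -0.55, adjusted p 5.4e-05) and had a median of 0.034 without PCL replicate 1. The mural list passed without PCL replicate 1 (0.35, adjusted p 0.00385) and had -0.19 without PCL replicate 3, where the endothelial median was -0.29. The endothelial receptor gene Tie1 had 49.4 ± 5.05 against 31.3 ± 4.10 FPKM (limma adjusted p 0.0646 over the list alone). Pdgfb, the growth factor that recruits pericytes, had 36.8 ± 5.47 against 23.5 ± 2.62 FPKM (limma adjusted p 0.0958 over the list alone), and Vegfa had 38.5 ± 2.27 against 27.1 ± 4.53.

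Lists for the response to mechanical and electrical stimulation did not pass the camera test. Mechanosensitive and voltage-gated calcium channel genes had a median log2 difference of -0.12, with the potassium channel gene Kcnk4 at 2.09 ± 0.880 FPKM in the PCL group and 0.764 ± 0.468 in the PLLARS_US group. Activity-regulated immediate early genes had a median of -0.14, with Ier2 at 52.6 ± 4.30 against 42.7 ± 4.47 FPKM, and YAP and TAZ targets one of 0.08, with Crim1 at 12.7 ± 2.32 against 21.6 ± 3.25. Heat shock genes had a median of 0.11, with Hspb1 at 38.5 ± 4.87 against 125 ± 124 FPKM. Hypoxia and glycolysis genes had a median of -0.03, with Adm, the adrenomedullin gene, at 15.1 ± 3.39 against 26.4 ± 3.43 FPKM. Cholesterol synthesis genes had a median of -0.11, nuclear-encoded oxidative phosphorylation genes -0.10 and mitochondrially encoded mRNAs 0.02. Skeletal muscle genes had a median of -0.13, adipocyte genes 0.37, epithelial genes -0.15 and cartilage and bone genes -0.20. Without PCL replicate 3 the lists of skeletal muscle (median 1.29, camera adjusted p 0.0479), adipocyte (0.21, 0.0298), heat shock (0.083, 0.0479), hypoxia (0.39, 0.00796), oxidative phosphorylation (0.080, 0.00796) and mitochondrially encoded genes (0.20, 0.00135) passed. Without PLLARS_US replicate 3 the heat shock (0.26, adjusted p 0.00176), cholesterol (-0.24, 0.00964) and mitochondrially encoded (0.17, 0.0232) lists passed, and the adipocyte median was -0.19. Without PLLARS_US replicate 1 the adipocyte (0.79, adjusted p 0.00123) and hypoxia (-0.43, 0.0301) lists passed and the skeletal muscle median was -1.60, without PLLARS_US replicate 2 the skeletal muscle list passed (2.18, adjusted p 0.000855), and without PCL replicate 2 the oxidative phosphorylation list (-0.19, adjusted p 0.00685). Across these stimulation, stress, metabolic and other tissue lists the camera adjusted p ran from 0.146 to 0.869. For the myelin, macrophage, T cell, B cell, endothelial, skeletal muscle and hypoxia lists the median was below 0 while camera, which compares a list with the other genes, pointed up; the mean of the B cell and hypoxia lists was above 0, and that of the YAP list was below 0 with a median above 0.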

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

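Leaving out the 2 muscle-rich libraries, the muscle covariate and the reduced forms of the added lists were chosen after the results were seen; the other alternatives were planned. The count of genes past an adjusted p of 0.05 with limma was 0 in the main analysis, with 960 at an unadjusted p under 0.05. A further log2 threshold of 1 on that analysis could only keep the 0. The count was also 0 under both other pseudocounts, both other filters, 3 other scalings, no trend, robust moderation and named gene models alone. It was 118 with array weights (2827 at an unadjusted p under 0.05) and 3 with the muscle covariate (Mx2, Oas1a and AABR07021804.1, the last named after its values were seen, smallest adjusted p 0.00334). Leaving out single libraries gave 0 to 3 genes. Array weights rest on weights estimated from 6 libraries; the cause of the other moves was not tested. Sample numbers recur in both groups, and the labels do not say whether they pair the rats. Residuals of same-numbered libraries correlated at -0.50, 0.15 and -0.32. With 3 libraries per group that residuals are centred on, these correlations cannot settle whether the numbers pair rats. With the replicate block, limma called 0 genes (543 at an unadjusted p under 0.05) and camera 7 lists. Across the groups, no library correlated best with the library of its own number. The planned DESeq2 and edgeR alternatives were not run because no counts were analysed, nor were annotation terms.

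Camera called 4 lists in the main analysis, 4 to 12 without single libraries (12 without PCL replicate 3), 10 without the 2 muscle-rich libraries, 0 with an estimated correlation, and fry called 1. The interferon list kept its direction throughout, with medians of 1.55 to 2.12 without single libraries, and lost its call with an estimated correlation (median 1.76, adjusted p 0.416). The cell division list (-0.57 to -0.46 without single libraries) lost it with an estimated correlation and with fry (median -0.53, adjusted p 0.785 and 0.123). The foreign body list (-1.65 to -0.43) lost it without PCL replicate 3 (adjusted p 0.609), PLLARS_US replicate 2 (0.119) or PLLARS_US replicate 3 (0.656), with no filter (-0.73), with an estimated correlation and with fry (-0.87 in both). The inflammatory list (-0.029 to 0.49, its median below 0 without PLLARS_US replicate 1) lost it without that library (adjusted p 0.964) or PCL replicate 1 (0.0528), under median-ratio scaling (0.40), without the 2 muscle-rich libraries (-0.08, adjusted p 0.961), with an estimated correlation and with fry (0.33 in both). Of the 34 other lists, 20 passed in at least 1 alternative and 23 changed direction in at least 1; the cause was not tested.

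Directions that turned, for a list those of its test, belonged to lists or genes that had not passed. Without the 2 muscle-rich libraries the medians were 0.0017 for cholesterol, -0.19 for endothelial, -0.045 for hypoxia, -0.24 for macrophage, -0.035 for MHC class II, -0.10 for mural, -0.19 for neutrophil, 0.043 for oxidative phosphorylation, -0.19 for skeletal muscle and -0.048 for YAP lists, and the genes that turned were Ache (0.086), Bag3 (-0.054), Ccl2 (-0.090), Chrnb1 (-0.040), Cxcr2 (-0.071), Fcmr (0.27), Kcnj8 (-0.0068) and Tnnt1 (-0.022). With fry, whose medians are those of the main analysis, the endoneurial (0.059), endothelial (-0.031), myelin (-0.12), skeletal muscle (-0.13) and T cell (-0.0036) lists turned. Median-ratio scaling turned the endoneurial (0.12) and skeletal muscle (-0.084) lists, Mcm6 (0.0034) and Pcna (0.021). Quantile normalization (-0.078) and a pseudocount of 0.1 (-0.38) turned the skeletal muscle list, and no filter the endothelial (-0.035) and epithelial (-0.044) lists. Array weights turned Fcmr (0.15), Ibsp (0.065), Mcm6 (0.032), Mt-atp8 (0.019) and Mt-nd3 (0.026). Leaving out single libraries turned the following, given with their lowest and highest values: adipocyte -0.19 to 0.79, axon guidance -0.11 to 0.22, cartilage and bone -0.42 to -0.036, cholesterol -0.24 to -0.039, endoneurial -0.21 to 0.35, endothelial -0.29 to 0.18, red blood cell -2.83 to 0.057, fibroblast -0.55 to 0.034, hypoxia -0.43 to 0.39, immediate early -0.28 to 0.0043, macrophage -0.34 to 0.15, MHC class II -0.44 to 0.24, mitochondrially encoded -0.12 to 0.20, mural -0.19 to 0.35, myelin -0.94 to 0.74, neurotrophic -0.21 to 0.27, neutrophil -0.032 to 0.90, oxidative phosphorylation -0.19 to 0.080, repair Schwann -0.55 to 0.48, skeletal muscle -1.60 to 2.18, T cell -0.13 to 0.22, YAP -0.092 to 0.18, Ache -0.56 to 0.076, Agrn -0.17 to 0.83, Bag3 -0.014 to 0.58, Cdh1 -1.07 to 0.23, Chrnb1 -0.19 to 1.24, Comp -0.59 to 0.12, Epcam -0.78 to 0.29, Erbb3 -0.0073 to 1.02, Fcmr -0.39 to 0.33, Krt10 -0.44 to 0.11, Mcm6 -0.16 to 0.023, Mt-atp8 -0.43 to 0.070, Mt-nd3 -0.27 to 0.060, Mt-nd4l -0.017 to 0.25, Mt-nd5 -0.053 to 0.27, Ngfr -0.34 to 1.77, Pcna -0.13 to 0.034, Pvalb -2.97 to 0.59, RT1-Db1 -0.60 to 0.011, Tenm2 -0.00095 to 0.91 and Tnnt1 -0.086 to 0.33. Lists that did not turn had these ranges without single libraries: alternatively activated macrophage -0.0032 to 0.28, angiogenic -0.36 to -0.078, B cell -0.21 to 0.28, calcium channel -0.23 to 0.0039, epithelial -0.44 to 0.012, heat shock -0.014 to 0.26, mast cell 0.068 to 1.31, metalloproteinase -0.53 to -0.090, neuronal -0.43 to -0.22, perineurial 0.054 to 0.33, Schwann lineage -0.0034 to 0.81 and synapse -0.19 to 0.24. Of 177 genes followed, 25 turned in any alternative and 24 passed in at least 1, all 24 with array weights.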

Other observations

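The 6 gene lists in this paragraph and their tests were added after the results were seen, and the genes named were chosen after their values were seen. Interferon-inducible GTPases were higher in the PLLARS_US libraries in 9 of 9 tested members, with a median log2 difference of 0.89. Igtp had 13.1 ± 1.99 FPKM in the PCL group and 29.7 ± 3.55 in the PLLARS_US group, Ifi47 28.2 ± 2.67 against 53.1 ± 4.64 and Gbp5 8.17 ± 0.745 against 22.1 ± 6.69. Genes of MHC class I antigen processing were higher in 13 of 14 cases, with a median of 0.28, among them the peptide transporter gene Tap1 at 16.4 ± 2.40 against 24.8 ± 2.45 FPKM and Tapbp at 28.8 ± 1.14 against 49.5 ± 11.9. Nucleic acid sensors went both ways: Zbp1 had 1.83 ± 0.821 against 7.87 ± 2.22 FPKM and Dhx58 5.71 ± 1.57 against 16.8 ± 3.89, while Irf3, the factor that relays their signal, had 45.2 ± 7.52 against 28.6 ± 5.15. The GTPase and sensor lists hold genes already named among those with the smallest p, such as Irgm, Ifih1, Ddx58 and Eif2ak2, so these lists were tested without such genes and without members of the interferon list. The 7 remaining GTPases then had a camera adjusted p of 3.0e-11 (adjusted p = 0.0695 with an estimated correlation, fry adjusted p 0.0120). They still held Igtp, Ifi47 and Gbp5, with limma adjusted p of 0.225, 0.225 and 0.242 over all genes. Because the lists were written after the results were seen, their reduced forms are not independent support either. The 13 remaining sensors, 7 of them higher, had a median of 0.10 and did not pass (camera adjusted p 0.101, adjusted p = 0.236 with an estimated correlation, fry adjusted p 0.0521). The MHC class I list lost no member and had a camera adjusted p of 1.4e-06 (adjusted p = 0.0372 with an estimated correlation, fry adjusted p 0.00638). The interferons themselves were near the floor, Ifnb1 being listed at 0 in the PCL libraries and at 0.220, 0 and 0.461 FPKM in the PLLARS_US libraries, and Ifng at 0, 0.123 and 0 against 0, 0.364 and 0.376. The 5 tested members of the list of interferons and receptors, all of them receptor genes, had a median of -0.28 (camera adjusted p 0.0786, adjusted p = 0.236 with an estimated correlation), and passed with fry in the lower direction (fry adjusted p 0.0269). The splicing factor and ribosomal protein lists count gene models, and some share a symbol, such as Crnkl1, Rpl21 and Rpl32. Their members are therefore not all distinct genes. Splicing factor models were lower in 25 of 35 cases with a median of -0.13 (camera adjusted p 0.0134, adjusted p = 0.422 with an estimated correlation, fry adjusted p 0.129). Cytoplasmic ribosomal protein models were higher in 68 of 77 cases with a median of 0.19 (camera adjusted p 4.1e-10, adjusted p = 0.345 with an estimated correlation, fry adjusted p 0.325). These medians kept their sign under 3 other scalings, from -0.14 to -0.07 for splicing factors and from 0.15 to 0.25 for ribosomal proteins.

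The tests of the interferon pattern were chosen after the pattern was seen. A larger share of macrophages, T cells and B cells together would raise their markers alike. The upper quartile of their 44 pooled markers was a log2 difference of 0.24, below the lower quartile of the interferon list at 1.04. The neutrophil and mast cell lists were not in that test. They had upper quartiles of 0.63 and 0.88, with 8 of 9 members higher in each. A pooled test cannot show a rise of 1 cell type alone, so a change in leucocytes is not excluded. Muscle in 2 libraries gave no account of the interferon pattern, since its median was 1.53 without PCL replicate 3 and PLLARS_US replicate 1. The median was 1.80 at its lowest over 3 other scalings. For rescaling to a common sum this could hardly have come out otherwise, because the summed FPKM of the libraries ran only from 499573 to 543169. Median-ratio scaling and quantile normalization do not rest on those sums, and gave medians of 1.82 and 1.80. They moved the median of all tested genes only from -0.042 to 0.015 and -0.0012, so neither was likely to remove the interferon difference. A difference in interferon response between these rats may underlie the pattern. That is a hypothesis drawn from these same data, and no test here addressed it directly. The conduit, the ultrasound, and any infection, housing or handling that followed the groups stay open and untested, because the labels separate none of them.

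Small non-coding RNA models were lower in the PLLARS_US libraries. Over 445 models the libraries held 83.2 ± 5.24 fragments per 1000000 in the PCL group and 45.4 ± 2.83 in the PLLARS_US group (SD, n = 3 each), a ratio of 0.546 (exact permutation test, two-sided p = 0.1, the smallest 3 against 3 can give). MicroRNA models had a ratio of 0.395, snoRNA models 0.506, U RNA models 0.570 and 7SK models 0.716, each without overlap between the groups and with the same exact permutation p of 0.1. The 5S rRNA models had a ratio of 0.560, but their groups overlapped (exact permutation p = 0.2). The median log2 difference of the 92 tested models ran from -0.89 to -0.67 over the scalings.

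The tests of the small RNA pattern were set before their results were seen, but the set of models was corrected after a first result, and the lengths of the coding models were compared with those of the small ones only afterwards. A first version of the name match had taken in 5 coding genes such as U2af1 and Snorc; with those genes the models outside listed genes gave a ratio of 0.919 in place of 0.540, which had met the bound set for unspliced host transcripts. A loss of short fragments cannot be told apart from a change in RNA. Protein-coding models spanning at most 1000 bases had a median log2 difference of 0.02 where the 92 tested small models had -0.73, which met the bound set against it. That bound was wrong because 0 of these 205 coding models were as short as the upper quartile of the small models, 144 bases. Up to the length of the longest tested small model, 334 bases, 20 coding models had a median of 0.007 and 218 other models one of -0.21. These values do not decide it, because the coding models were still longer than most small models. Genomic DNA in the PCL libraries cannot be told apart from a change in RNA: 85 olfactory and vomeronasal receptor genes had a summed FPKM ratio of 0.798, between the bounds set, and their groups overlapped. Unspliced host transcripts as a source of these reads also cannot be told apart from a change in RNA. The 173 models outside listed genes had a ratio of 0.540, and the 134 inside an expressed gene on the same strand 0.523. The rest of the 445 models were in neither class. A model outside the genes in the table may still lie in a transcript it does not list. The kit as named does not state strand, so models antisense to a gene may also hold its reads.

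Of the tests on splits, that of genes at an unadjusted p under 0.05 was chosen after the result was seen. The comparison of the interferon list over the splits was not set beforehand. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 0 genes with limma, with 960 at an unadjusted p under 0.05, and the highest other split 1. A count of 0 is reached by all 10 splits whatever the data, so that comparison says nothing about chance. At the unadjusted level 4 splits, the real one included, gave as many as 960 genes, and the highest other gave 2061. Camera at the preset correlation called 4 lists in the real split and up to 18 in the others, and all 10 splits called at least as many as the real one. The other splits, which mix the groups, called 9 to 18 lists. A small camera adjusted p at the preset correlation can thus arise from a structure of the samples that does not follow the groups. Such p values are weak evidence alone, and the source of that structure was not tested. The interferon list had an absolute median of 1.76 in the real split and at most 1.04 in the others. That list was already seen to separate the groups, and every other split mixes them. The real split was therefore bound to rank high, and the ranking says nothing about chance.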
